A study of Homo sapiens with 21 samples.

How the data were processed

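Bulk RNA of Expi293F cells was measured in 21 libraries, 3 for each of 7 groups, by oligo(dT)-primed, single-end sequencing toward the 3′ ends of transcripts with unique molecular identifiers. Groups and replicate numbers were taken from the sample labels, which call the replicates independent biological replicates. The submitters' processing notes name FastQC 0.12.1, STAR 2.7.11, SAMtools 1.22.1, MultiQC 1.32, featureCounts of Subread 2.1.1, edgeR 4.0.16 and the genome GRCh38, without the annotation release or the role of each tool. Per the labels, the authors deposited 1 table with an expected count for each of 78894 genes and library, not normalized. In it 26.5% of the cells above 0 were not whole numbers. The authors also deposited CPM, which equalled each count scaled to a library total of 1000000 to a relative deviation of 2.3e-05. The plan had assumed whole counts, so the expected counts were rounded before the count models were fitted. Symbols were those of the table, with Ensembl identifiers. Names were blank for 36134 genes, which held 3.01% to 4.39% of the counts of a library, and 43 of them were given a symbol from an older annotation used for names only.

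Genes were kept by filterByExpr of edgeR with the 7 groups, which left 16191. One fit of 7 group means to all 21 libraries used TMM factors and the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with 13 comparisons, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Averaged groups weighed equally. For 33 fixed gene lists camera of limma 3.58.1 was run with a preset correlation of 0.01, adjusted over the lists within a comparison. An estimated correlation was used with the main fit only, so list calls in all other settings rest on the preset one. Members of a list were counted with p adjusted over all genes and also adjusted over the list alone. Library composition was tested by an exact two-sided permutation test over the 1330 ways to choose 3 of 21 libraries. Tables and pictures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

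The rule named, for each comparison, up to 8 genes per direction with the largest change among genes called with a log2 fold change of at least 1. It asked for a mean of at least 10 CPM in the higher group, an official symbol and no overlap of libraries, and smaller changes filled up the places. It also named the 4 called members with the smallest p of each list that was called or had at least 5 called members, and 17 genes chosen in advance for every comparison with Control. A gene named in at least 1 comparison with Control may be given for all 6. The text names fewer genes than the rule gave, and which ones was decided when their stability was known. Stability over all 884 values that the rule named is therefore given with the alternatives.

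Alternatives fixed in advance were other scaling factors, DESeq2 1.42.0, no expression filter or a stricter one of 30 counts in 3 libraries, only the groups compared, the replicate number as a block, thinning to 309875 counts, leaving out each library, an estimated correlation for the lists and a threshold of 0.01 for shared genes. Log2 depth as a covariate, libraries above 1000000 counts, libraries above 3000000 counts and 2 settings for library composition were added after the data were seen. No Dual library had over 3000000 counts, so that setting gives no value for Dual. It keeps 1 library each of Single L and Triple 2 and 2 of Triple 1, and a lone library is assumed to vary like the other groups. The genes shared by the 6 comparisons were set beside 10 simulations of unchanged groups, in which the Control libraries were drawn too, while the plan had spoken of the same Controls. Of 13 comparisons, 4 were tested on simulated data with 200 changed genes among 16191. Changes of 0.5, 1 and 2 in log2 were recovered for 37.3%, 80.6% and 90.9% of genes in Single L against Control, and for 28.4%, 70.1% and 87.9% in Dual against Control. For Triple 3 against Control the shares were 61.2%, 89.6% and 98.5%, and for Triple 3 against Triple 1 41.8%, 74.6% and 95.5%, with 5.3% to 6.7% of calls false. Sequence reads, splicing and plasmid sequences were not analysed here.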

Results

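Messenger RNA was measured by single-end sequencing toward the 3′ ends of transcripts in Expi293F cells, a human embryonic kidney line grown in suspension. Plasmid transfection of such cells is used to make recombinant adeno-associated virus vectors. The 21 libraries fell into 7 groups of 3 biological replicates: untransfected Control, Single L and Single H with the lower and the higher concentration of a single plasmid, Dual, and Triple 1, Triple 2 and Triple 3. What each plasmid carried, how the triple groups differed and when cells were collected are not in the labels. Total counts were 10399385, 8454622 and 7359487 in Control replicates 1 to 3, 1386527, 4377923 and 866415 in Single L, and 7664714, 5787282 and 4235753 in Single H. They were 453707, 1214754 and 1478117 in Dual, 7860688, 310285 and 7995634 in Triple 1, 8917068, 1532966 and 612815 in Triple 2, and 4407699, 4052093 and 3727502 in Triple 3. Depth thus differed up to 33.5-fold between libraries, and the Control libraries were among the deepest. No group was transfected without plasmid. Comparisons with Control therefore cannot separate plasmid DNA from the transfection procedure, and depth differs in them too. A count of 3 in the shallowest library corresponds to 9.67 CPM. Unless said otherwise, changes are log2 fold changes ± SE from the edgeR fit of all 21 libraries (n = 3 per group) with adjusted p, and 16191 genes were tested.

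Mitochondrially encoded mRNAs, which specify subunits of the respiratory chain and ATP synthase, took 7.84% ± 0.708 (SD, n = 3) of the counts in Control and 5.43% ± 0.512 (SD, n = 18) in the transfected libraries. Cytosolic ribosomal protein genes took 16% ± 0.883 (SD, n = 3) in Control and 20.2% ± 1.89 (SD, n = 18) in the transfected libraries. Both differences had p = 0.000752 in an exact two-sided permutation test, the smallest that its 1330 splits allow, and 0.0015 after adjustment over 4 measures. The 10 most abundant genes took 11.1% and 10.44% (exact permutation p = 0.38). With mitochondrial mRNAs left out of the total, those shares were 7.74% and 9.43%, and the difference took the other sign (exact permutation p = 0.0301). The number of genes with a count was 33274 in Control and 24810 in the transfected libraries (exact permutation p = 0.0165, adjusted p = 0.0221). After thinning every library to the smallest total it was 16006 and 15863 (exact permutation p = 0.353), and without Control replicate 2 the adjusted p for all counts was 0.211.

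Within groups, 1369 genes changed with sequencing depth, 930 of them falling and 439 rising with it. Among them were 59 of 85 cytosolic ribosomal protein genes and 31 of 58 nuclear genes of oxidative phosphorylation, all lower in deeper libraries, with median slopes of −0.08 for each list per doubling of depth. Leukocyte and erythroid marker genes, which kidney-derived cells are not known for, had a median slope of −0.47, and 10 of 15 fell with depth. Without HBB, their summed level was 90.1 ± 24.2 CPM in Control, 251 ± 32.3 in Single L, 136 ± 21.9 in Single H and 311 ± 147 in Dual (SD, n = 3 each). It was 276 ± 269 in Triple 1, 279 ± 250 in Triple 2 and 158 ± 16.8 in Triple 3 (SD, n = 3 each). The list, tested with HBB (8.49 ± 0.70 in Triple 3), was higher than other genes in 5 of the 6 comparisons against Control, all but Single H (adjusted p = 0.102). Of its 15 members 1 to 9 were called, and 0 to 13 adjusted over the list alone. With an estimated correlation none of the 6 list tests was called (adjusted p = 0.348 to 0.684). The Triple 1 call was lost without Triple 1 replicate 2 (adjusted p = 0.139). The Triple 2 call was lost without Control replicate 1 (0.0577) or Triple 2 replicate 3 (0.271), and a Single H call appeared without Control replicate 3 (0.0263). For a comparison of 3 libraries with 3 an exact test cannot give a p under 0.1, so single genes and lists were tested with edgeR and camera.

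**Figure D1:**
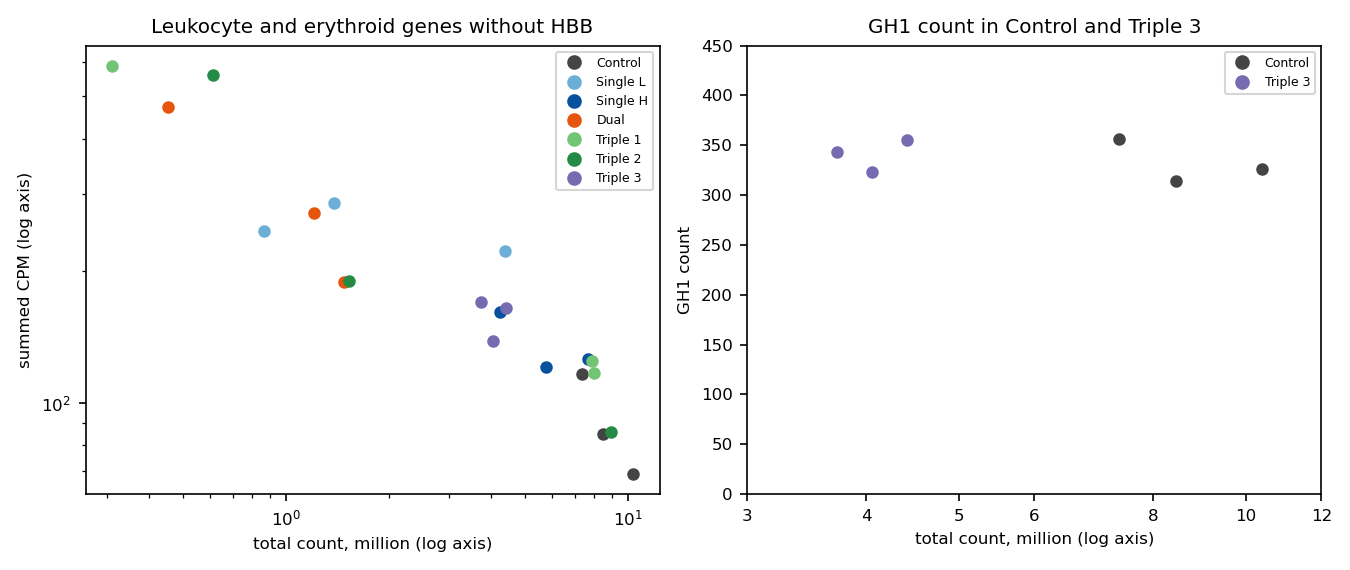
Left, summed CPM of 19 leukocyte and erythroid genes, without HBB, against the total count of each of the 21 libraries, both on log axes. Right, the GH1 count, on an axis from 0, in the 3 Control and 3 Triple 3 libraries against the total count on a log axis: it lay between 314 and 356 while totals ran from 3727502 to 10399385.

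GH1, the gene of pituitary growth hormone, was called higher in every transfected group, in Triple 3 only after scaling to depth. It stood at 38.9 ± 8.62 CPM in Control, 10210 ± 963 in Single L, 10650 ± 239 in Single H and 7339 ± 510 in Dual (SD, n = 3 each). Triple 1 had 7809 ± 326 CPM, Triple 2 had 7699 ± 334 and Triple 3 had 84.1 ± 6.88 (SD, n = 3 each). The log2 fold changes over Control ran from 7.75 ± 0.15 in Triple 2 to 8.23 ± 0.15 in Single L, and the value was 1.24 ± 0.13 in Triple 3 (adjusted p = 8.6e-10 or below in all 6). As counts, GH1 had 323 to 355 in the Triple 3 libraries and 314 to 356 in the deeper Control libraries, so the Triple 3 change rests on the scaling to depth. Its placental relatives GH2 and CSH1 had 7.28 to 8.44 in the same 5 groups, and 1.20 ± 0.19 and 1.36 ± 0.98 in Triple 3, where CSH1 did not pass the test (adjusted p = 0.32). These genes are nearly identical in sequence, so their separate counts are uncertain. HBB, the adult beta-globin gene, stood at 129 ± 30.3 CPM in Control and 42720 ± 688 in Triple 3 (SD, n = 3 each), a log2 fold change of 8.49 ± 0.70 (adjusted p = 7.1e-07). HBB was also higher in Single L (1.65 ± 0.55) and Dual (1.93 ± 0.57), but those calls were lost with log2 depth as a covariate (0.67 and 0.41), with thinned counts (1.47 and 1.76), without the filter (1.56 and 1.79) and without some single libraries. The Single L value was 1.48 to 1.71 (adjusted p = 0.071 or above) without Control replicate 1 or 2 or any 1 Single L library. The Dual value was 1.76, 1.84 or 1.58 without Control replicate 1, Control replicate 2 or Dual replicate 1. In Triple 2 it was 1.42 ± 0.57 (adjusted p = 0.08) and passed the test at 1.92 without Triple 2 replicate 1. The list of genes whose sequence is often used in expression plasmids, which holds GH1, GH2, CSH1 and HBB, had 3 to 8 of 12 members higher and none lower in all 6 comparisons, and 3 to 8 adjusted over the list alone. Its median log2 fold changes were 0.88 to 1.84 (adjusted p = 0.000128 or below). The call held in 5 comparisons with an estimated correlation and was lost in Triple 3 (adjusted p = 0.0994 with an estimated correlation). These counts and tests take GH1, GH2 and CSH1 as separate genes, although they may share reads.

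**Figure D2:**
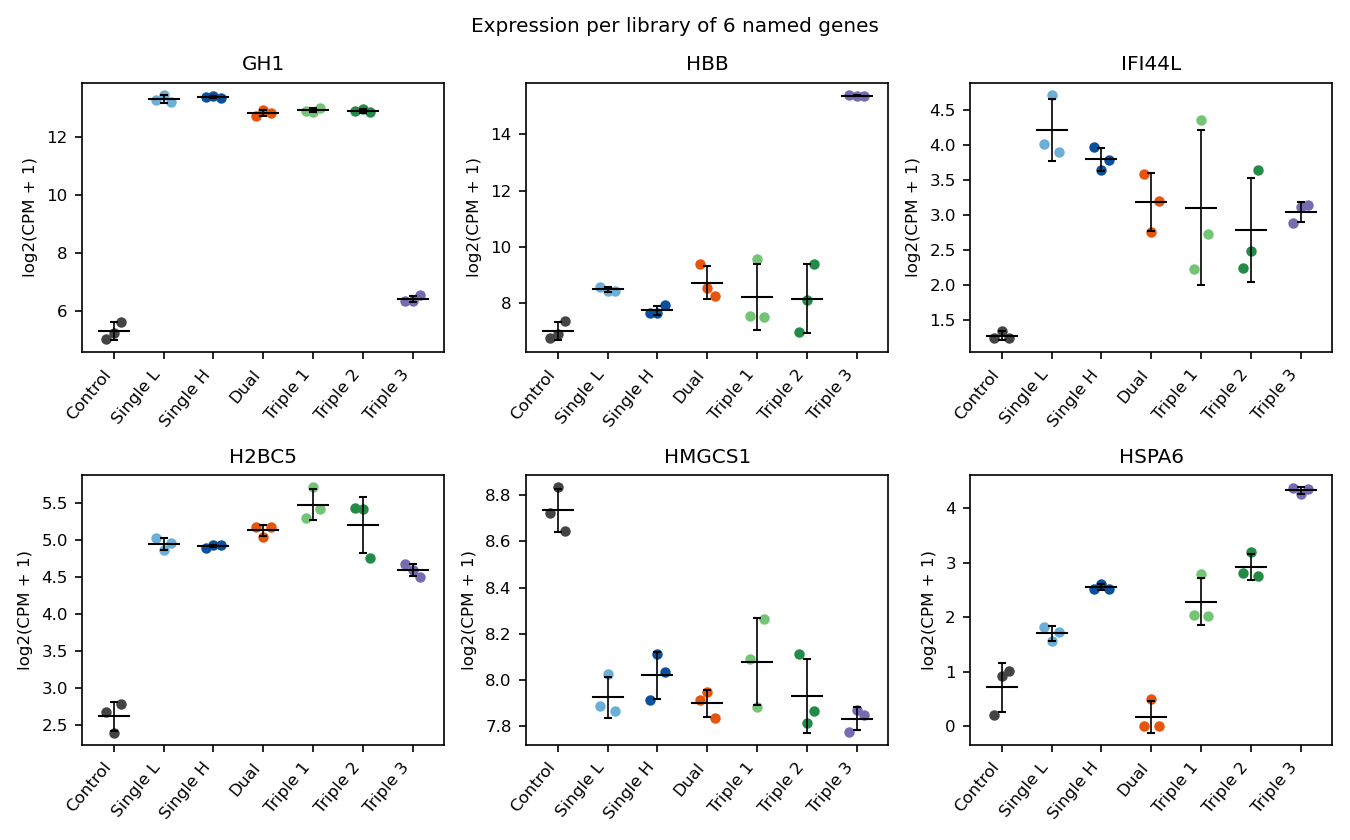
CPM of 6 genes in each library, as log2(CPM + 1), in the 7 groups. Points are libraries, horizontal lines are group means and error bars are 1 SD (n = 3). GH1 was high in every transfected group but Triple 3, and HBB was at 42280 to 43510 CPM in Triple 3.

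Between 4153 and 4825 of the 16191 genes tested passed the test in each comparison against Control, 2264 to 2503 of them higher and 1889 to 2327 lower. Between 399 and 970 of these changed by at least 2-fold. In all 6 comparisons, 1500 genes passed in the same direction, 894 higher and 606 lower, among 8758 called in any. Only 16 genes were called in opposite directions in any of them. For pairs of comparisons, 1342 to 1834 genes were higher and 1028 to 1505 lower in both, where independent lists of those sizes would share 318.5 to 386.2 and 235.9 to 310.2. In 10 simulations of unchanged groups, drawn with their Controls, at most 4 genes were called in a comparison, none in all 6, and at most 1 by a pair. They held no change with depth, so they cannot tell a response to transfection from an effect of depth. With so few calls, they also cannot show how far the shared Controls raise the overlap among called genes. All 6 comparisons use the same 3 Control libraries, so their lists of calls are not independent. Over genes, the slope with depth within groups correlated with the 6 fold changes at r = −0.47 (Single L and Dual) to −0.27 (Triple 2). Across genes, which are not independent replicates, the fold changes of pairs correlated with r = 0.635 to 0.868 and a covariance of 0.159 to 0.297. The simulations gave 0.105 to 0.399 and 0.0149 to 0.0296, and 3 Control libraries are too few to be divided. The 1500 genes shared were 894 higher and 606 lower with TMM scaling, and 1158 higher and 393 lower with upper-quartile scaling. DESeq2 gave 742 (608 higher, 134 lower), log2 depth as a covariate 624 (496 higher, 128 lower) and thinned counts 95. More were lower without the expression filter (571 higher, 670 lower), and the sides were about even without Control replicate 2 (668 and 670). Without Control replicate 1, 869 genes were shared. Over the 6 comparisons, genes higher made up 37.7% to 48.1% without the filter and 46.3% to 51.1% without 1 of the Control libraries, so the larger side depended on the settings.

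Interferon-stimulated genes rose in all 6 groups. Of 45 members measured, 34 rose and none fell in Single L, 31 rose and 1 fell in Single H, 20 rose and 2 fell in Dual, and 15 to 17 rose and 1 or 2 fell in the triple groups. Adjusted over the list alone, 15 to 38 rose and 1 or 2 fell. The median log2 fold change was 1.33 in Single L, 0.83 in Single H, 0.79 in Dual, 0.33 in Triple 1, 0.40 in Triple 2 and 0.51 in Triple 3. IFI44L rose by 4.03 ± 0.27 in Single L, by 3.29 ± 0.24 in Single H and by 1.66 ± 0.36 in Triple 2 (2.34 without Triple 2 replicate 1). ISG15, a ubiquitin-like modifier, rose by 1.54 to 3.36, IFIT1, which binds foreign RNA, by 1.16 to 2.95, and IFITM1, a membrane protein that restricts virus entry, by 0.86 to 2.44. The camera test called the list in all 6 (adjusted p = 0.000108 or below). The call held with an estimated correlation in Single L and Single H (adjusted p = 0.00935 and 0.00629 with an estimated correlation). It was lost in Dual (0.111), Triple 1 (0.117), Triple 2 (0.133) and Triple 3 (adjusted p = 0.0994 with an estimated correlation). The leukocyte markers given above were also higher in 5 of these groups.

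The list of interferons and NF-κB target cytokines was called in Single L alone (6 of 22 higher, 8 adjusted over the list alone, median 0.75, adjusted p = 0.0116), and not with an estimated correlation (adjusted p = 0.331 with an estimated correlation). That call was lost without Single L replicate 2 (adjusted p = 0.0574). Calls appeared in Triple 1 without Triple 1 replicate 1 (0.0462) or 3 (0.0482), in Triple 2 without Triple 2 replicate 1 (0.0103) and in Triple 3 without Control replicate 3 (0.0408). The chemokine gene CCL5 rose in all 6 groups by 2.82 to 4.24 (SE 0.40 to 0.64), an uncertain amount, since the Control libraries had 1 to 4 counts and 1 library each of Dual and Triple 1 had 0. CXCL10, another chemokine gene, rose by 2.52 ± 0.36 in Single L and by 1.33 ± 0.34 in Single H. CXCL8, which attracts neutrophils, was at 1.64 ± 0.56 in Single L (adjusted p = 0.042). It missed the threshold there without any single library of the 6 compared (1.43 to 1.88, adjusted p = 0.063 to 0.13). In the other 5 groups it was at 0.69 to 1.44 and did not pass, but each of them had some other setting in which it did, for Triple 2 without Triple 2 replicate 1 (1.98, adjusted p = 0.048). The mean CPM of CXCL8 lay near that of LYZ, a leukocyte gene, in Single L (16.34 and 18.01) and Triple 1 (20.78 and 21.45). The same held in Triple 2 (18.36 and 18.91), but not in Dual (13.69 and 28.49). Within groups, 5 of the 22 genes of this list fell with depth. The CXCL8 values therefore cannot be told from the pattern of the leukocyte markers. IFNB1, the interferon-beta gene, had at most 4 counts in any library and was not tested. Genes of MHC class I antigen presentation were called higher in Single L (9 of 17, median 0.56), Dual (9, 0.53), Triple 1 (3, 0.31) and Triple 3 (3, 0.28), and 2 to 12 rose adjusted over the list alone. With an estimated correlation none of the 6 was called (adjusted p = 0.305 to 0.684), and 9 of the 17 genes fell with depth within groups. The Triple 1 call was lost without Triple 1 replicate 2 (0.12). The Triple 3 call was lost without Control replicate 1 (0.122), Triple 3 replicate 1 (0.0802) or 3 (0.0537). A Triple 2 call appeared without Control replicate 3 (0.0362) or Triple 2 replicate 1 (0.000291). PSMB9, an immunoproteasome subunit, rose by 1.44 ± 0.26 in Single L and by 1.67 ± 0.33 in Dual. The list of 12 nucleic acid sensors and adaptors was not called in any comparison, with medians from −0.12 to 0.07 against Control (adjusted p = 0.594 or above). Its members MAVS, the adaptor of RNA sensors, fell in all 6 groups by 0.37 to 0.88 (SE 0.09 to 0.16), and PQBP1, which acts with the DNA sensor cGAS, rose by 0.48 to 0.96 (SE 0.10 to 0.13; in Triple 2 0.77 without Triple 2 replicate 1, and 0.23 and no call with only its 1 library above 3000000 counts).

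Counts of replication-dependent histone genes rose in all 6 groups. Their transcripts normally lack poly(A) tails, and the libraries were oligo(dT)-primed, so total histone mRNA was not measured. Between 17 and 21 of 24 members rose and at most 1 fell, and 18 to 22 rose adjusted over the list alone. The median log2 fold change was 1.59 in Triple 3 to 2.15 in Triple 2, and the camera test called the list in all 6 also with an estimated correlation (adjusted p = 0.00161 or below with an estimated correlation). H2BC5 rose by 2.29 to 3.08 (SE 0.13 to 0.20), H1-2 by 2.07 to 2.77 (SE 0.11 to 0.13) and H2BC12 by 1.79 to 2.14. H2AC18 rose by 1.86 to 3.12, and its near-identical copy H2AC19 makes that count uncertain. Genes of G2/M and mitosis fell in 5 of the 6 groups, all but Triple 1, with 11 to 17 of 38 members lower and 1 to 3 higher and medians of −0.25 to −0.14. The call held with an estimated correlation in Triple 3 alone (adjusted p = 0.0432 with an estimated correlation, 0.091 to 0.24 in the other groups called). Adjusted over the list alone, 13 to 19 fell. The Single H call was lost without Single H replicate 1 (adjusted p = 0.0511). A call in Triple 1, where 10 members fell with a median of −0.10 (adjusted p = 0.0501), appeared without Control replicate 1 (0.0342), 2 (0.0336) or 3 (0.0213) or Triple 1 replicate 1 (0.0192). TOP2A, the topoisomerase that untangles replicated DNA, fell by 0.30 to 0.49 (SE 0.08 to 0.09). MKI67, a proliferation marker, was lower in all 6 by 0.35 to 0.75 (adjusted p = 0.0027 to 0.048). It was at −0.96 in Single L without Single L replicate 2 and at −0.49 in Dual without Dual replicate 2, and both calls were lost with log2 depth as a covariate (−0.46 and −0.65). Its call was lost in Single H without Single H replicate 1 (−0.38), and in Triple 1 without Control replicate 1 (−0.42) or 3 (−0.37) or Triple 1 replicate 1 (−0.45) or 3 (−0.33). In Triple 3 it was lost without Control replicate 1 (−0.37) or 3 (−0.31) or without any 1 Triple 3 library (−0.39 to −0.29). The list of DNA replication and G1/S genes, with 5 to 9 of 50 higher and 5 to 11 lower, was not called (adjusted p = 0.0655 or above). It was called lower in Single L without Control replicate 1 (0.0438), Control replicate 3 (0.0392) or Single L replicate 2 (0.0481), and in Dual without Control replicate 3 (0.0474). The same held in Triple 1 without Control replicate 1 (0.0342), Control replicate 3 (0.0234), Triple 1 replicate 1 (0.0144) or Triple 1 replicate 3 (0.0328).

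Genes of DNA damage response and repair fell in all 6 groups, with 12 to 15 of 33 lower and 2 to 5 higher, 13 to 18 lower adjusted over the list alone, and medians of −0.40 to −0.16 (adjusted p = 0.00414 or below). With an estimated correlation no call held (adjusted p = 0.125 to 0.3 with an estimated correlation). ATM, the kinase that responds to double-strand breaks, fell by 0.57 to 0.88 (SE 0.10 to 0.17), and PRKDC, the kinase of DNA end joining, by 0.36 to 0.78 (SE 0.09 to 0.10). Targets of p53 fell in all 6 as well, with 10 to 13 of 27 lower and 1 to 3 higher, the same ranges adjusted over the list alone, and medians of −0.34 to −0.12 (adjusted p = 0.025 or below). The call held with an estimated correlation in Single H (adjusted p = 0.0279 with an estimated correlation) and was lost in the others (0.0604 to 0.227). CDKN1A, the cell cycle inhibitor p21, fell by 0.45 to 0.90 (SE 0.08 to 0.09) and ZMAT3, an RNA-binding protein, by 0.67 to 1.01 (SE 0.09 to 0.15).

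Sterol and lipid synthesis genes fell in every transfected group. Of 25 genes of cholesterol biosynthesis and SREBP2 targets, 13 to 17 fell and 2 to 4 rose (13 to 17 and 2 to 5 adjusted over the list alone), with medians of −0.48 in Triple 2 to −0.24 in Single L (adjusted p = 0.00153 or below). The call held with an estimated correlation in Single H, Triple 1, Triple 2 and Triple 3 (adjusted p = 0.00352 to 0.0351 with an estimated correlation) and was lost in Single L (0.15) and Dual (0.111). HMGCS1, which makes HMG-CoA, fell by 0.49 to 0.79, the squalene epoxidase gene SQLE by 0.65 to 0.82 and INSIG1, a sterol-regulated anchor, by 0.58 to 0.97 (SE 0.08 to 0.09). Of 17 genes of fatty acid synthesis and SREBP1 targets, 6 to 9 fell and none rose, over all genes and adjusted over the list alone (medians −0.34 to −0.24, adjusted p = 0.00134 or below, 0.0782 to 0.129 with an estimated correlation). FASN, the fatty acid synthase gene, fell by 0.51 to 0.82 and SCD, a desaturase gene, by 0.56 to 0.65 (SE 0.08 to 0.11). The 9 sterol efflux and LXR targets were not called (medians 0.16 to 0.52, adjusted p = 0.185 or above).

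Cytosolic ribosomal protein genes rose in all 6 groups, 46 of 85 in Triple 3 to 81 in Dual with at most 1 lower, and 52 to 82 adjusted over the list alone. Their medians were 0.29 to 0.63 (adjusted p = 5.79e-10 or below), and no call held with an estimated correlation (adjusted p = 0.111 to 0.503 with an estimated correlation). RPSA rose by 0.66 to 1.11 (SE 0.12). Nuclear genes of oxidative phosphorylation rose too, 18 of 58 in Triple 3 to 48 in Dual with at most 2 lower, and 26 to 50 adjusted over the list alone (medians 0.22 to 0.55, adjusted p = 0.000128 or below, 0.125 to 0.546 with an estimated correlation). COX6A1, a subunit of cytochrome oxidase, rose by 0.56 to 1.01 (SE 0.12 to 0.13). With log2 depth as a covariate, the medians in Dual were 0.44 for the ribosomal protein genes and 0.29 for oxidative phosphorylation. Both lists were still called there by camera with the preset correlation of 0.01 (adjusted p = 6.65e-58 and 1.19e-15). The correlations estimated in the main fit were 0.673 to 0.682 and 0.52 to 0.531. They were not used with the covariate, so whether these 2 calls would hold with them is not known. Mitochondrially encoded mRNAs fell in all 6, with 5 to 9 of 13 lower and none higher, 7 to 10 lower adjusted over the list alone, and medians of −0.64 to −0.31 (adjusted p = 0.0397 or below, 0.141 to 0.51 with an estimated correlation). The Single L call was lost without Control replicate 1 (0.0847), Control replicate 3 (0.0933) or Single L replicate 2 (0.0574), and the Single H call without Single H replicate 1 (0.0589). MT-ATP8, a subunit of ATP synthase, fell by 0.92 ± 0.11 in Triple 1, and MT-CYB, a subunit of complex III, fell there by 0.82 ± 0.12. Ribosome biogenesis genes were called higher in Single H (20 of 36), Triple 1 (15), Triple 2 (14) and Triple 3 (15), with 12 to 21 over the 6 comparisons adjusted over the list alone. The medians in those 4 groups were 0.20 to 0.28, and no call held with an estimated correlation (adjusted p = 0.0575 to 0.371 with an estimated correlation). The Triple 2 call was lost without Triple 2 replicate 1 (0.233), and a Single L call appeared without Single L replicate 3 (0.0149). RRP12 rose by 0.65 to 0.96 (SE 0.11 to 0.19) in all 6 groups, but in Dual not without Dual replicate 2 (0.52).

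Heat shock chaperone genes rose in Single H (15 of 25), Triple 1 (12), Triple 2 (15) and Triple 3 (17), with 1 or 2 lower and medians of 0.20 to 0.32 (adjusted p = 0.0017 or below). The call held with an estimated correlation in Triple 3 (adjusted p = 0.0302 with an estimated correlation) and was lost in the other 3 (0.0799 to 0.313). Over the 6 comparisons, 10 to 18 rose and 1 to 4 fell adjusted over the list alone. A Single L call appeared without Single L replicate 3 (adjusted p = 0.0224). DNAJB1, a cochaperone of HSP70, rose by 0.71 ± 0.10 in Single L, 0.82 ± 0.08 in Single H and 1.06 ± 0.08 in Triple 3. HSPH1, a nucleotide exchange factor of HSP70, rose by 0.61 ± 0.09 in Single H, 0.48 ± 0.10 in Triple 1 and 0.97 ± 0.09 in Triple 3. After thinning it was at −0.05 in Triple 1. HSPA8, the constitutive HSP70, rose by 0.37 to 0.62 (SE 0.09) in all 6. HSPA1A, an inducible HSP70, fell by 0.39 to 0.99 (SE 0.09 to 0.13), and its count is uncertain because HSPA1B is nearly identical. The ATF4 list of the integrated stress response was called lower in Single H (16 of 38), Dual (14), Triple 1 (18) and Triple 2 (13), with 3 or 4 higher and medians of −0.26 to −0.14, and 6 to 18 lower over the 6 comparisons adjusted over the list alone. The call held in Single H with an estimated correlation (adjusted p = 0.0279 with an estimated correlation, 0.122 to 0.133 in the other 3). The Dual call was lost without Dual replicate 2 (0.0641), and the Triple 2 call without Control replicate 2 (0.0638) or Triple 2 replicate 1 (0.106). Its member SHMT2, of serine metabolism, fell by 0.42 to 0.53, while DDIT3, the transcription factor CHOP, rose in all but Triple 1 (0.18 ± 0.14), by 0.47 ± 0.13 in Single H to 1.02 ± 0.20 in Dual. The DDIT3 call in Single H was lost without Control replicate 1 (0.35). The unfolded protein response list was not called (medians −0.06 to 0.04, adjusted p = 0.581 or above). HSPA5, its main chaperone gene, was at −0.27 to 0.01, and its call in Single L (−0.27 ± 0.09) was lost without Single L replicate 1 (−0.26) or 3 (−0.21), while it was at −0.44 without Single L replicate 2.

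**Figure D3:**
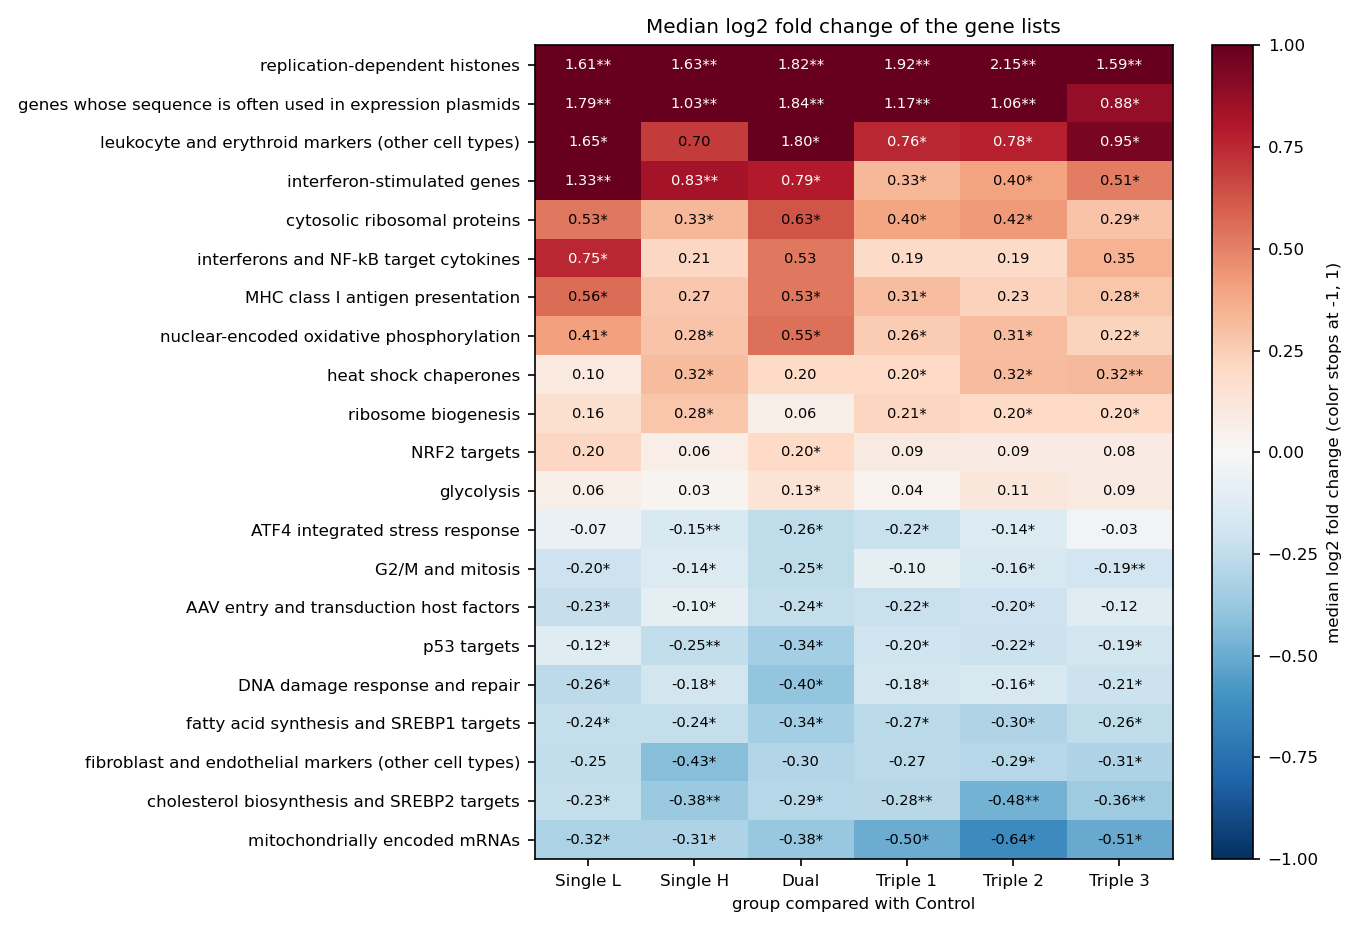
Median log2 fold change of each gene list in the 6 groups compared with Control, for the 21 lists called in at least 1 of them. A single asterisk marks a camera call with the preset correlation and 2 asterisks a call that also held with an estimated correlation. Histone genes had medians of 1.59 to 2.15 and mitochondrially encoded mRNAs of −0.64 to −0.31.

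Host factors of AAV entry and transduction were lower in 5 groups, all but Triple 3 (adjusted p = 0.09), with 9 to 12 of 31 lower and 1 to 3 higher and 11 to 13 lower adjusted over the list alone. The medians were −0.24 to −0.10, and no call held with an estimated correlation (adjusted p = 0.081 to 0.263 with an estimated correlation). The Single L call was lost without Single L replicate 2 (0.0574), and a Triple 3 call appeared without Control replicate 1 (0.0418) or Triple 3 replicate 2 (0.0319). KIAA0319L, the AAV receptor gene, fell by 0.27 to 0.61 (SE 0.09 to 0.15), in Triple 3 not without Triple 3 replicate 1 (−0.27) or 3 (−0.26). WDR11, which acts in endosome sorting, fell by 0.50 to 1.10 (SE 0.10 to 0.18), and its value in Triple 2 went from −0.56 to −1.20 without Triple 2 replicate 1. Fibroblast and endothelial markers were lower in Single H (4 of 7), Triple 2 (2) and Triple 3 (3), with the same counts adjusted over the list alone and medians of −0.43, −0.29 and −0.31 (adjusted p = 0.0289, 0.0424 and 0.0403, 0.169 to 0.231 with an estimated correlation). The Single H call was lost without Control replicate 2 (0.0736) or Single H replicate 1 (0.0566), and the Triple 2 call without Control replicate 2 (0.0705) or Triple 2 replicate 1 (0.205). The Triple 3 call was lost without Control replicate 2 (0.0779), Triple 3 replicate 2 (0.0912) or Triple 3 replicate 3 (0.0527). COL6A1, a collagen gene of that list, fell in all 6 groups by 0.80 to 1.02 (SE 0.08 to 0.13). NRF2 targets (6 of 24 higher, median 0.20, adjusted p = 0.0381, 0.268 with an estimated correlation) and glycolysis genes (8 of 19, median 0.13, adjusted p = 0.0133, 0.305 with an estimated correlation) were called in Dual alone. Adjusted over the list alone, 6 and 9 rose there. The glycolysis call was lost without Control replicate 1 (0.0539), and that of NRF2 targets without Control replicate 1 (0.0947) or 3 (0.0821) or Dual replicate 1 (0.14) or 3 (0.0562). A call of NRF2 targets in Single L appeared without Control replicate 2 (0.0341). The oxidoreductase gene NQO1 rose by 0.70 to 0.91 (SE 0.11 to 0.20) in all 6, in Dual not without Dual replicate 3 (0.75, adjusted p = 0.052).

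Among immediate early genes, 2 to 6 of 24 were higher and 7 or 8 lower, and the list was not called (medians −0.16 to 0.22, adjusted p = 0.0816 or above). It was called lower without Control replicate 3 in Single L (0.0386) and Single H (0.0452). JUN fell in all 6 groups by 0.33 to 0.73 (SE 0.09 to 0.10) and MYC by 0.49 to 0.59 (SE 0.09 to 0.12). FOS was at −0.60 ± 0.20 in Single H and −0.25 to 0.19 elsewhere, and the Single H call was lost without Control replicate 1 (−0.52) or Single H replicate 3 (−0.49). No call against Control was made for the lists of apoptosis regulators (medians −0.10 to 0.06, adjusted p = 0.286 or above), lysosome and TFEB genes (−0.04 to 0.14, 0.236), autophagy (−0.01 to 0.08, 0.42) or hypoxia targets (−0.18 to −0.12, 0.149). Metallothioneins (−0.20 to 0.06, 0.295), actin, SRF and YAP targets (−0.15 to 0.04, 0.259) and kidney and neural lineage genes (−0.01 to 0.20, 0.252) were not called either. Adjusted over the list alone, at most 10 of 36 lysosome genes rose and at most 9 fell.

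Single genes outside these lists changed in all 6 groups as well. IRS4, an insulin receptor substrate abundant in embryonic kidney lines, fell by 1.28 to 1.62 (SE 0.11 to 0.12), ID2, an inhibitor of differentiation, by 0.84 to 1.27 (SE 0.09 to 0.12) and TENM1, a teneurin, by 1.14 to 1.79 (SE 0.16 to 0.32). AMH, the gene of anti-Müllerian hormone, rose by 1.49 to 2.25 (SE 0.14 to 0.27), and its neighbour SF3A2, a splicing factor gene, fell by 0.94 to 1.46 (SE 0.09 to 0.16). LARP4B-DT, a divergent transcript whose reads could not be told from an overlapping gene, was higher by 2.51 to 3.36 (SE 0.25 to 0.47).

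Single L against Control asked what transfection with the lower concentration of 1 plasmid changed. Besides the GH1 family, the interferon-stimulated genes that rose included IFI44L (4.03 ± 0.27), ISG15 (3.36 ± 0.22), IFIT1 (2.95 ± 0.21) and IFI6 (2.89 ± 0.17), which limits mitochondrial cell death. In all, 4595 genes passed the test, 2503 higher and 2092 lower, and 726 changed by at least 2-fold. The share higher was 54.5%, 66% with upper-quartile scaling, 66.4% with DESeq2 and 44.3% without the expression filter. In CPM without the TMM factors, the libraries of the groups did not overlap for 8110 genes, where interchangeable libraries give 10%, or 1619. The TMM factors were 1.068 to 1.106 in Control and 0.915 to 1.006 in Single L, so a shift in composition can add to this count. The same holds for the other groups below. DESeq2 called 2679 genes, and counts thinned to the smallest library gave 842.

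Single H against Control asked the same of the higher concentration. IFI44L (3.29 ± 0.24) and ISG15 (2.55 ± 0.20) rose. Of the amino acid response genes, PCK2, a gluconeogenic enzyme, fell by 0.49 ± 0.09 and DDIT4, an mTOR inhibitor, by 0.60 ± 0.09. Among the 6 comparisons with Control, PCK2 was called in 4 and DDIT4 in 5. Of 4825 genes called, 2498 were higher and 2327 lower, and 399 changed by at least 2-fold. Genes higher made up 51.8%, 67.2% among the 1909 genes that DESeq2 called and 44.7% without the expression filter. The libraries did not overlap in CPM without TMM factors for 7904 genes, against 1619 (10%) for interchangeable libraries. Thinned counts gave 253 calls, and without Control replicate 1 there were 3180.

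Dual against Control asked what transfection with 2 plasmids changed, in the group with the lowest median depth. H2AC18 rose by 3.12 ± 0.17, while the microRNA host gene MIR34AHG was lower by 2.00 ± 0.50, a count that overlapping genes could share. LYZ, the lysozyme gene of leukocytes, was at 2.25 ± 0.70 (adjusted p = 0.027), and its call was lost without Control replicate 1 (1.93), Dual replicate 1 (1.90) or Dual replicate 2 (2.23). Of 4482 genes called, 2375 were higher and 2107 lower, and 970 changed by at least 2-fold. Genes higher made up 53%, 65.3% with upper-quartile scaling, 66% with DESeq2 and 37.7% without the expression filter. The libraries did not overlap in CPM without TMM factors for 8331 genes, against 1619 (10%) for interchangeable libraries. Thinned counts gave 1163 calls and log2 depth as a covariate 1129, and without Dual replicate 3 there were 2566.

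Triple 1 against Control asked what transfection with the first triple composition changed. H2BC5 rose by 3.08 ± 0.13, and BMP2, a bone morphogenetic protein gene, was lower (−1.40 ± 0.20). BMP2 was called lower in all 6 groups (−1.54 to −0.93), so it is not particular to Triple 1. PCK2 fell by 0.60 ± 0.10. Of 4529 genes called, 2371 were higher and 2158 lower, and 436 changed by at least 2-fold. Higher genes were 52.4%, 67.1% with upper-quartile scaling, 74.6% among the 1601 genes that DESeq2 called and 48.1% without the expression filter. The libraries did not overlap in CPM without TMM factors for 6914 genes, against 1619 (10%) for interchangeable libraries. Thinned counts gave 422 calls, and without Triple 1 replicate 1 there were 2085.

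Triple 2 against Control asked the same of the second composition. The pseudogenes IRS3P (4.11 ± 0.25) and KLKP1 (4.03 ± 0.25) rose. Both were called higher in all 6 groups, by 1.33 to 4.11 and by 1.82 to 4.30. CCNE1, the cyclin of entry into S phase, rose by 1.35 ± 0.11, and PCK2 fell by 0.73 ± 0.11. CCNE1 was called in 5 of the 6 groups (0.45 to 1.35 over all 6). Of 4300 genes called, 2278 were higher and 2022 lower, and 514 changed by at least 2-fold. The share higher was 53%, 63.6% with upper-quartile scaling, 69.1% among the 2091 genes that DESeq2 called and 46.6% without the expression filter. The libraries did not overlap in CPM without TMM factors for 6354 genes, against 1619 (10%) for interchangeable libraries. Thinned counts gave 574 calls.

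Triple 3 against Control asked the same of the third composition. Besides HBB, the genes HSPA6 (4.85 ± 0.24), KLKP1 (4.30 ± 0.23) and IRS3P (4.10 ± 0.24) rose. HSPA6, a strictly inducible HSP70 gene, stood at 0.683 ± 0.472 CPM in Control and 19.1 ± 0.81 in Triple 3 (SD, n = 3 each). The HSP70 partner BAG3 rose by 0.92 ± 0.10, the HSP90 partner CHORDC1 by 0.78 ± 0.08 and TRIB3, a pseudokinase of the ATF4 response, by 0.78 ± 0.10. Among the 6 comparisons with Control, HSPA6 and CHORDC1 were called in 5, BAG3 in 4 and TRIB3 in this 1 only. Of 4153 genes called, 2264 were higher and 1889 lower, and 446 changed by at least 2-fold. The share higher was 54.5%, 69.4% among the 1629 genes that DESeq2 called and 45.6% without the expression filter. The libraries did not overlap in CPM without TMM factors for 7720 genes, against 1619 (10%) for interchangeable libraries. Thinned counts gave 218 calls, and there were 2665 without Control replicate 1 and 2716 without Triple 3 replicate 3.

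Single H against Single L asked what the plasmid concentration changed. BST2, the virus tethering protein tetherin, was lower at the higher concentration by 0.80 ± 0.12 (adjusted p = 0.0003), and IFITM1 by 0.75 ± 0.11 (adjusted p = 0.0003). MPST, a sulfur transferase gene, was lower by 0.55 ± 0.11, the unnamed gene ENSG00000288681 by 0.68 ± 0.12, and HCFC1, a transcription coregulator gene, higher by 0.54 ± 0.10. The unnamed gene was named because so few genes passed, after its value was seen. GH1 differed by −0.02 ± 0.11. These 5 calls, 1 higher and 4 lower, compare with 1576 genes at an unadjusted p under 0.05 and with 1 call by DESeq2. Of 45 interferon-stimulated genes 2 were lower and none higher, 19 lower adjusted over the list alone (median −0.51, adjusted p = 8.64e-16, 0.0689 with an estimated correlation). Cytokine genes (median −0.34, none called, 3 lower adjusted over the list alone, adjusted p = 0.00364, 0.324 with an estimated correlation) moved the same way, and that call was lost without Single L replicate 2 (0.0582). Leukocyte markers (median −0.83, adjusted p = 0.000143, 0.324 with an estimated correlation) and ribosomal protein genes (median −0.23, 16 lower adjusted over the list alone, adjusted p = 7.19e-25, 0.324 with an estimated correlation) also did. Oxidative phosphorylation genes were lower (median −0.16, adjusted p = 5.8e-09, 0.377 with an estimated correlation), but lay at a median of 0.01 with only libraries above 3000000 counts, where Single L keeps 1 library. In all 13 lists were called here, 5 higher and 8 lower, and none with an estimated correlation. Heat shock chaperone genes were higher (median 0.16, 4 higher and 1 lower adjusted over the list alone, adjusted p = 2.57e-06, 0.239 with an estimated correlation). HCFC1 was lost without Single L replicate 1 (0.48) or 3 (0.53) or Single H replicate 2 (0.52). With log2 depth as a covariate 3 of the 5 calls were kept and no gene was called higher, so HCFC1 was lost there too. MPST was lost without Single L replicate 1 (−0.51) or 3 (−0.42) or Single H replicate 2 (−0.49) or 3 (−0.53). Without Single L replicate 1, Single L replicate 2 or Single H replicate 2 there were 3, 103 and 2 calls.

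Dual against the mean of Single L and Single H asked what a second plasmid changed. The slope with depth within groups correlated over genes with these fold changes at r = −0.28. GH1 was at −0.45 ± 0.10 (adjusted p = 0.079) and passed without Single L replicate 3 (−0.46, adjusted p = 0.038). No gene passed edgeR's test, 1769 had an unadjusted p under 0.05, DESeq2 called 23, and without Single L replicate 3 edgeR called 20. As lists, interferon-stimulated genes were lower (median −0.27, none of 45 called, 3 lower adjusted over the list alone, adjusted p = 0.00458, 0.396 with an estimated correlation), and that call was lost without Dual replicate 3 (0.11). Ribosomal protein genes (median 0.22, adjusted p = 2.31e-34, 0.396 with an estimated correlation) and oxidative phosphorylation genes (median 0.19, adjusted p = 8.24e-14, 0.396 with an estimated correlation) were higher, with no member called in either count. Leukocyte markers were higher (median 0.59, adjusted p = 0.0101, 0.479 with an estimated correlation), not without Dual replicate 1 (0.51), and they were lower with log2 depth as a covariate (median −0.21, adjusted p = 0.0477).

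The mean of the triple groups against the mean of the single groups asked how the triple process differed from the single one. Its fold changes correlated over genes with the slope with depth within groups at r = 0.29. Interferon-stimulated genes were lower in the triple groups, 20 of 45 with none higher, and 28 adjusted over the list alone. The median was −0.67 (adjusted p = 6.17e-55, 0.00147 with an estimated correlation). IFI44L was lower by 1.65 ± 0.15, IFIT1 by 1.42 ± 0.12, IFI27 by 1.14 ± 0.13, IFITM1 by 1.08 ± 0.08 and PLSCR1, a scramblase gene, by 0.63 ± 0.07. Leukocyte markers had a median of −0.36 in the same comparison, with no member but HBB called. Their camera test (adjusted p = 0.985) included HBB, which was higher by 2.48 ± 0.38. It therefore does not show that the other members were unchanged. The median was −0.58 with only libraries above 3000000 counts, where Single L and Triple 2 keep 1 library each. H1-2 was higher by 0.34 ± 0.07, and histone genes as a list had a median of 0.19 (2 of 24 higher, 6 adjusted over the list alone, adjusted p = 0.00114, 0.317 with an estimated correlation). That list call was lost without Single L replicate 2 (0.188). MT-ATP8 was lower by 0.36 ± 0.07, though not past the threshold without Single L replicate 1 (−0.33, adjusted p = 0.05). Mitochondrially encoded mRNAs as a list were lower (2 of 13, 10 adjusted over the list alone, median −0.26, adjusted p = 1.74e-10, 0.154 with an estimated correlation). GH1 (−2.64 ± 0.07), CSH1 (−2.77 ± 0.14) and HBB (2.48 ± 0.38) differed as well, beside the low GH1 and high HBB of Triple 3 given above. The plasmid sequence list that holds them was called lower (3 of 12 lower, 1 higher, adjusted p = 1.16e-67, 1.39e-06 with an estimated correlation), with 4 lower adjusted over the list alone. That test takes the near-identical GH1, GH2 and CSH1 as separate genes. In all 90 genes were called, 40 higher and 50 lower, and DESeq2 called 39. There were 53 calls without Single L replicate 1, 59 without Triple 1 replicate 1, 57 without Triple 1 replicate 3, 51 without Triple 2 replicate 1 and 58 without Triple 3 replicate 1, and 7 after thinning.

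The mean of the triple groups against Dual asked how the triple process differed from the dual one. Its fold changes correlated over genes with the slope with depth within groups at r = 0.38. GH1 (−2.19 ± 0.08) and GH2 (−2.04 ± 0.08) were lower in this mean, which holds the low values of Triple 3: GH1 stood at 84.1 CPM there, 7809 in Triple 1, 7699 in Triple 2 and 7339 in Dual. The plasmid sequence list, which holds these genes, was lower in the mean too (3 of 12, 4 lower and 1 higher adjusted over the list alone, adjusted p = 1.42e-33, 3.2e-05 with an estimated correlation). Near-identical GH1, GH2 and CSH1 were separate members in that test. The angiogenic factor gene VEGFA (1.04 ± 0.23), the lipase gene ABHD4 (1.23 ± 0.30), DNAJB1 (0.53 ± 0.11) and HSPH1 (0.51 ± 0.11) were higher. IFITM1 (−0.80 ± 0.15) and the isoprenoid synthesis genes IDI1 (−0.36 ± 0.07) and FDPS (−0.38 ± 0.08) were lower. Each of these 7 calls was lost without Dual replicate 2 or 3 (adjusted p = 0.061 to 0.25), with VEGFA at 0.99 and 1.28 and IFITM1 at −0.76 and −0.75. Ribosomal protein genes (38 of 85 lower, 80 adjusted over the list alone, median −0.31, adjusted p = 6.03e-46) and oxidative phosphorylation genes (13 of 58 lower, 35 adjusted over the list alone, median −0.28, adjusted p = 1.35e-21) were lower. Interferon-stimulated genes (4 of 45 lower, 10 adjusted over the list alone, median −0.39, adjusted p = 0.000168) were lower and heat shock chaperone genes (4 of 25 higher, 1 lower, 8 and 1 adjusted over the list alone, median 0.18, adjusted p = 0.000611) higher. All 4 calls were lost with an estimated correlation (adjusted p = 0.338 with an estimated correlation for each). Leukocyte markers, with the HBB that is high in Triple 3 among them, had a median of −0.88 (adjusted p = 0.084). They were called higher with log2 depth as a covariate (median 0.12, adjusted p = 0.0102). Of 519 genes called, 170 were higher and 349 lower. Genes higher made up 32.8%, 54.1% without the expression filter, 22.4% with upper-quartile scaling and 20.7% among the 576 genes that DESeq2 called. Calls numbered 182, 27 and 9 without Dual replicates 1, 2 and 3, and 254 without Triple 1 replicate 3. They numbered 243 without Triple 2 replicate 1, 848 without Triple 2 replicate 2, 324 without Triple 3 replicate 2 and 14 with log2 depth as a covariate.

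Triple 2 against Triple 1 asked how those triple compositions differed. IRS3P (2.04 ± 0.22) and KLKP1 (1.87 ± 0.21) were higher in Triple 2, as was CCNE1 (0.85 ± 0.12), which was lost without Triple 2 replicate 1 (0.72). GH1 differed by −0.02 ± 0.11. All 25 genes called were higher. DESeq2 called 9, and 11 were called without Triple 1 replicate 3. No gene was called by edgeR after thinning. Of the lists, that of cholesterol biosynthesis was called lower (median −0.12, none of 25 called in either count, adjusted p = 0.0126, 0.477 with an estimated correlation), and the call was lost without Triple 1 replicate 3 (0.0982) or Triple 2 replicate 1 (0.11). Ribosomal protein genes and leukocyte markers (adjusted p = 0.996 each) were called higher without Triple 1 replicate 2 (0.0186 each) or Triple 2 replicate 1 (9.24e-10 and 0.017).

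Triple 3 against Triple 1, asked for the same reason, had HBB higher by 7.22 ± 0.68 and GH1 (−6.53 ± 0.14) and GH2 (−6.10 ± 0.14) lower. HSPA6 was higher by 2.62 ± 0.21, BAG3 by 0.65 ± 0.11, TRIB3 by 0.76 ± 0.12 and DDIT3 by 0.73 ± 0.14, the last not without Triple 1 replicate 3 (0.63). IRS3P (2.03 ± 0.21) and KLKP1 (2.14 ± 0.20) were higher as well, and H2BC5 (−0.80 ± 0.11) and H2AC18 (−0.93 ± 0.12) lower. The ATF4 list was higher (6 of 38, 15 adjusted over the list alone, median 0.21, adjusted p = 5.56e-09, 0.00623 with an estimated correlation). So were heat shock chaperones (6 of 25, 8 higher and 1 lower adjusted over the list alone, median 0.10, adjusted p = 9.65e-08, 0.0758 with an estimated correlation). Targets of p53 were higher (2 of 27, 6 adjusted over the list alone, adjusted p = 0.00704, 0.212 with an estimated correlation), not without Triple 3 replicate 1 (0.0686). Histone genes were lower (5 of 24, 11 adjusted over the list alone, median −0.31, adjusted p = 5.57e-10, 0.0491 with an estimated correlation). The plasmid sequence list was lower as well (3 lower and 1 higher of 12 in both counts, adjusted p = 4.94e-81, 5.42e-08 with an estimated correlation). It holds the near-identical GH1, GH2 and CSH1 as separate members. Of 113 genes called, 65 were higher and 48 lower, and DESeq2 called 30. There were 37 without Triple 1 replicate 1, 42 without Triple 1 replicate 3, 51, 68 and 56 without Triple 3 replicates 1, 2 and 3, and 6 after thinning.

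Triple 3 against Triple 2 asked about the remaining pair and had HBB higher by 7.07 ± 0.67 and GH1 (−6.51 ± 0.14) and GH2 (−6.08 ± 0.14) lower. HSPA6 (1.62 ± 0.20), TRIB3 (0.72 ± 0.13) and the stress cytokine gene GDF15 (0.69 ± 0.12) were higher, and H2BC5 (−0.77 ± 0.12) and H1-2 (−0.59 ± 0.10) lower. HBB was at 6.56 to 7.82 without 1 of the libraries, and its call was lost with only the 2 groups compared (7.01, adjusted p = 0.27). Without Triple 2 replicate 1 the calls of HSPA6 (1.31), TRIB3 (0.38), GDF15 (0.70) and H2BC5 (−0.71) were lost, and without Triple 2 replicate 2 that of H1-2 (−0.47). The ATF4 list was higher (2 of 38 in both counts, median 0.12, adjusted p = 0.000607, 0.00947 with an estimated correlation), as were p53 targets (2 of 27, 5 adjusted over the list alone, median 0.17, adjusted p = 6.45e-05, 0.0559 with an estimated correlation). Histone genes were lower (6 of 24, 11 adjusted over the list alone, median −0.41, adjusted p = 2.72e-13, 0.00947 with an estimated correlation). The plasmid sequence list was lower as well (3 lower and 1 higher of 12 in both counts, adjusted p = 1.14e-88, 2.63e-08 with an estimated correlation). It holds the near-identical GH1, GH2 and CSH1 as separate members. Ribosomal protein genes (median −0.12, adjusted p = 1.62e-07, 0.789 with an estimated correlation) and oxidative phosphorylation genes (median −0.08, adjusted p = 0.00445, 0.789 with an estimated correlation) were lower. With only libraries above 3000000 counts, where Triple 2 keeps 1 library, both lists were called higher instead (medians 0.12 and 0.13, adjusted p = 8.23e-05 and 0.000526, if the lone library varies like the other groups). Of 45 genes called, 21 were higher and 24 lower, and DESeq2 called 4 higher and 15 lower. There were 25 without Triple 2 replicate 2, 22, 16 and 16 without Triple 3 replicates 1, 2 and 3, and 6 after thinning.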

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

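Of the tests in this part, the reassignments of libraries were planned before the results were seen, and the tests of the 3 patterns were written after the patterns were seen.

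Leukocyte and erythroid transcripts stood above Control most in groups with shallow libraries. RNA or reads carried over from other libraries or cells could give a contribution that weighs more in small libraries, and the median slope within groups was −0.48 per doubling of depth, below 0 for 14 of 14 members without HBB. Induction by transfection could raise them in part. Members without HBB had 20 calls against Control in the main fit and 10, not necessarily the same, with log2 depth in the model. The list's median log2 fold change fell with it, from 1.73 (median SE 0.66) to 0.25 (0.40) in Dual and from 1.68 (0.50) to 0.73 (0.32) in Single L; the other 4 groups had 0.68 to 0.93 (0.42 to 0.50) before and 0.20 to 0.53 (0.24 to 0.29) after. A single slope with log2 depth need not remove a carried-over contribution fully, so the calls left with it do not show induction. As counts, the list without HBB summed to 716, 719 and 857 in Control and 724, 560 and 633 in the shallower Triple 3 libraries. Neither explanation is excluded, and both may hold.

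GH1, GH2 and CSH1 were high in every transfected group but Triple 3, where HBB was high instead. Reads shared between near-identical genes could account for GH2, whose ratio to GH1 had a mean of 9.9% and a coefficient of variation of 3.4% over 15 libraries, where counting alone gives 3%, while CSH1, at 0.63 ± 0.11% (SD) of GH1, was not tested for it. An erythroid cell program in Triple 3 is excluded, since 10 other erythroid genes summed to 1 to 1.28 times the Control mean in the 3 Triple 3 libraries while HBB was 331 times Control. Transcripts of the transfected plasmids remain possible and could not be told from host transcripts: GH1 differed by −0.02 ± 0.11 between the plasmid concentrations, which a saturated or an equal uptake could also give.

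Interferon-stimulated genes were lower in the triple than in the single groups, by a median of −0.67. A difference in depth is excluded as the cause, since the median was −0.65 with log2 depth in the model. Leukocyte RNA carried over was undecided over all groups, where the leukocyte median without HBB lay 0.31 (0.11 to 0.46) above that of the interferon list. A test of Triple 3 against Single H alone was added because of that, and there the difference was 0.55 (0.27 to 0.76). The leukocyte median lay at 0.14 and the interferon median at −0.4, Triple 3 minus Single H. Both intervals come from resampling the genes of the lists, not libraries, and this pair was chosen after the first result. Carry-over is therefore not excluded, though the medians had opposite signs in that pair. A part from carried-over leukocyte RNA stays open. So does a weaker interferon response to the triple plasmids or a difference in time or dose, which could not be tested.

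The libraries of each comparison were also reassigned to groups, and the number of reassignments with at least as many calls as the real one, itself included, was counted. For 3 against 3 libraries there are 10 ways to divide them, too few for a share under 0.05. The real grouping alone (1 of 10) reached its count in Single L (4595, highest other 0), Single H (4825, 1), Dual (4482, 0), Triple 1 (4529, 11), Triple 2 (4300, 0) and Triple 3 (4153, 0) against Control. The same held for Single H against Single L (5, 0), Triple 3 against Triple 1 (113, 6) and Triple 3 against Triple 2 (45, 0). For Triple 2 against Triple 1, 2 of 10 reached 25 calls, and another division gave 329, which points to structure among those libraries other than the groups. For Dual against the single groups a real count of 0 is reached by any division (84 of 84), so this test says nothing. The highest other gave 271 calls, which points to structure in that division, and the median was 0. The combined groups were tested in a fit of 2 merged groups, which gives other counts than the main one. Triple against single had 11 calls, reached by 4 of 100 random divisions with a highest other of 88, and triple against Dual had 378, reached by 1 of 100 with a highest other of 191.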

How the results depend on the processing

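The tests with log2 depth, with libraries above 1000000 or 3000000 counts and the thinned number of genes with a count were chosen after the data were seen. Of all 884 gene values that the naming rule gave, 202 lost their call without some library and none reversed, 505 lost it in some other setting and 16 reversed, all with counts thinned, among them HSPH1 in Triple 1 (−0.05) and CCNE1 in Triple 1 (−0.31). Of 429 list tests, 129 lost their call with an estimated correlation and 30 kept it, none reversed. In other settings 16 list values reversed: 4 without a library, 5 with log2 depth, and 1 and 6 above 1000000 and 3000000 counts. With RLE factors, 879 of 884 gene values stayed. Thinning left 842 genes called for Single L, 253 for Single H, 1163 for Dual, 422 for Triple 1, 574 for Triple 2 and 218 for Triple 3 against Control. It left 5 for Dual against single, 7 for triple against single, 50 for triple against Dual, 0 for Triple 2 against Triple 1, 6 for Triple 3 against Triple 1, 6 for Triple 3 against Triple 2, 95 shared genes and 102 list calls, as fewer counts allow. DESeq2 called 2679 for Single L, 1909 for Single H, 1601 for Triple 1, 2091 for Triple 2 and 1629 for Triple 3 against Control. It called 1 for Single H against Single L, 23 for Dual against single, 39 for triple against single, 9, 30 and 19 for Triple 2 against 1, 3 against 1 and 3 against 2, and 742 shared genes. With log2 depth there were 2066 for Single L and 1129 for Dual against Control, 14 for triple against Dual, 62, 223 and 91 among the triple groups and 624 shared genes. Libraries above 3000000 counts, 1 each in Single L and Triple 2, 2 in Triple 1 and none in Dual, gave (a lone library is assumed to vary like the other groups) 2782 for Single L against Control, 14 for Single H against Single L, 140 for triple against single and 100, 190 and 282 among the triple groups, and those above 1000000 gave 18 for Single H against Single L. Without a filter there were 53 for Single H against Single L and 24 for Dual against single. With only the groups compared there were 93 for Single H against Single L and 13, 239 and 8 among the triple groups. Shared genes at an adjusted p under 0.01 numbered 695, and list calls with an estimated correlation 30. The replicate number as a block gave 1 call for Dual against single and 52 for triple against single, and a check of the pairing found a correlation over 0.1 in 1 of 21 pairs of groups, so replicate numbers were not taken as pairs. The leukocyte list in Dual against single reversed with log2 depth (adjusted p = 0.0477), and the share of the 10 most abundant genes reversed without mitochondrial mRNAs (exact permutation p = 0.0301). The number of genes with a count, lower after transfection, did not differ after thinning (exact permutation p = 0.353 alone and 0.38 adjusted with the other measures). Except where fewer counts, genes or libraries explain a value, the cause was not tested.

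Leaving out each library gave 3345 to 4506 calls for Single L, 3180 to 4476 for Single H, 2566 to 4505 for Dual, 2085 to 4336 for Triple 1, 3054 to 4115 for Triple 2 and 2665 to 3908 for Triple 3 against Control. It gave 2 to 103 for Single H against Single L, 0 to 20 for Dual against single, 51 to 129 for triple against single, 9 to 848 for triple against Dual, and 11 to 30, 37 to 124 and 16 to 54 among the triple groups. Shared genes ran from 869 to 1464. List calls were counted over the comparisons that hold the group, so their number depends on how many those are. The fewest were 31 without Dual replicate 1, where the main fit had 40 in the same 3 comparisons. The most were 104 without Control replicate 3, where the main fit had 97 in the same 6. The adjusted exact permutation p ran from 0.00175 to 0.0105 for mitochondrial and for ribosomal protein shares, from 0.208 to 0.684 for the 10 most abundant genes and from 0.00702 to 0.211 for genes with a count.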

Other observations

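Expected counts of GH1 in the 3 Control and 3 Triple 3 libraries lay between 314 and 356 although their totals ran from 3727502 to 10399385. Over 18 libraries without Triple 3, the count of HBB rose with the total by a slope of 0.54 ± 0.059 on log2 scales, where a fixed share would give 1. For the summed leukocyte and erythroid genes the slope was 0.49 ± 0.061 over 21 libraries.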
